A study of Felis catus with 15 samples.

How the data were processed

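The data are 15 RNA-seq libraries from the corpus, the middle region of the epididymis, of the domestic cat (Felis catus). They form 3 groups of 5 libraries each: fresh tissue, tissue pieces kept in culture (explants), and explants cultured with extracellular vesicles, which are small membrane-bound particles released by cells. Per the series text, the vesicles came from the caput, the first region of the epididymis. Per the labels' protocols, total RNA was extracted with a Qiagen kit and libraries were made with the TruSeq Stranded mRNA kit. A short code in the labels carries D0 for fresh tissue and D3 for both cultures, and its meaning is not given in the sources used here. Whether the replicates come from separate animals is not given either, so the p-values measure the spread between these samples. Within each group, libraries are named by their replicate number ("culture 3").

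The values analysed are raw counts per gene, deposited by the authors as 1 table of 38995 genes and 15 libraries. The submitters' processing notes name Trimmomatic 0.38, HISAT2 2.1.0, Bowtie2 2.3.4.1 and StringTie 2.1.3b, with no role or order for any of them. The genome build, the gene annotation, the counting program and the strand setting are not given in the sources used here. The kit is stranded, but with the strand setting of the counts unknown, reads of genes overlapping on opposite strands may not have been told apart. How reads matching several genes were counted is not given either. Values for members of gene families with similar copies are therefore uncertain. That caution applies to the S100A8 and S100A9, RNASE, PATE, WFDC, SPINK and beta-defensin families named in the results. The genes carry NCBI gene identifiers. All 38995 matched a RefSeq gene table of assembly F.catus_Fca126_mat1.0, which was used for names only, and 0 table entries lacked an identifier. No genome sequence was used, so no gene position, GC content or length was computed.

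Total counts ranged from 17308800 to 27420200 per library. Genes with low counts were left out with edgeR's filterByExpr at its default settings (minimum count 10, minimum total 15). This kept 18038 genes and left out 20957. Of the tested genes, 3878 have no symbol of their own. Counts were scaled by the trimmed mean of M values (TMM) and fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest), with the group as the only term and all 15 libraries in 1 fit with 12 residual degrees of freedom. This quasi-likelihood test was 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 18038 genes. Fold changes are log2 values of the first group over the second, and each standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. Levels per library are log2 CPM (counts scaled to the effective library size), computed with a prior count of 2. A fold against a group with a count of 0 in all its libraries was taken against 3 counts over the whole group and is a lower bound. With 1 to 3 counts in the group, the ratio of scaled counts is given with its exact 95% binomial interval. Such intervals and bounds, and the Wilson intervals of shares, cover counting error only.

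Gene lists for cell types and processes, 35 in all, were tested against all other genes with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of each comparison. The same test with an estimated correlation, and fry, were run as alternatives. A list needed 5 tested genes. The list of erythroid genes had 1 and was not tested, which left 34. List medians did not change when genes at 0 counts were set to their bound. The lists share members: 6 complement genes and 6 caput-associated genes, for example, also belong to other lists. Beside the count of called members over all genes tested, members were also counted with p adjusted over the list alone.

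The comparisons, tests, gene lists, named genes and main alternatives were fixed before the data were examined. The rule for named genes took, per comparison, the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean log2 CPM of 1 or more and the same sign in all 5 same-numbered differences. It added up to 4 members with the smallest adjusted p of every list described, and 13 genes fixed whatever their values, of which 12 are named. Some genes that the rule picks are not analysed here one by one, and no other gene took their place, so fewer members are named for some lists. Where no gene was called, the 10 genes with the smallest p are given as values. Another 9 genes (ATF4, ASNS, CHAC1, CLU, WFDC2, MFGE8, EPCAM, FAS and CAMP) were named after their values were seen, because they go against their list or mark its type.

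The alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, relative log expression and upper-quartile scaling, no filter, a filter at 1 CPM in 5 libraries, the replicate number as a block, fits of the 2 compared groups alone, a test against a 1.5-fold change (glmTreat), and fits without each replicate number or each single library. Upper-quartile scaling moved the median log2 fold change of all genes by -0.105 in culture with vesicles against fresh tissue, and by -0.0958 in culture against fresh tissue. Added after the data were seen were gene lists without culture 3, the block without culture 3, the removal of the 13 mitochondrially encoded protein genes, and a covariate for the level of the fibroblast list.

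The groups share replicate numbers, so it was checked whether same-numbered libraries deviate together from their group means. The correlation across genes was 0.508, 0.588, 0.181, 0.602 and 0.418 for replicates 1 to 5 between the 2 cultures, and 0.242 to 0.362 between culture with vesicles and fresh tissue. Every pair exceeded 0.1, so the numbers were taken to pair these samples. The pairing comes from the data and not from the labels. The closest pair of libraries, culture 1 and culture with vesicles 1, differed by a chi-square of 11.9 per gene, so none are duplicates.

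The gene tests were checked on simulated counts drawn from the libraries' own means and sizes, with 200 changed genes per simulation. For the comparison of the 2 cultures, 4.48% of genes changed 1.5-fold, 24.5% of genes changed 2-fold and 70.0% of genes changed 4-fold were recovered, and 5.48% of calls were false. For culture against fresh tissue the recovered shares were 2.09%, 29.6% and 70.9%. For culture with vesicles against fresh tissue they were 3.88%, 34.0% and 74.2%. The simulated libraries were drawn independently, which leaves out that same-numbered libraries deviate together, so these shares are no exact rates for the real libraries. Comparisons that share a group of libraries were also computed with that group split into separate parts, and beside 20 simulations of unchanged groups. Library measures were compared with exact permutation tests that regroup libraries without regard to replicate number. List levels were compared over same-numbered pairs with exact sign-flip tests. Both were 2-sided.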

Results

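Transcript levels were measured by RNA-seq in the corpus of the domestic cat epididymis, the duct in which sperm mature after leaving the testis. Of the 15 libraries, 5 came from fresh tissue, 5 from explants in culture, and 5 from explants cultured with extracellular vesicles of the caput, the region upstream of the corpus. Total counts were 17751500 to 24841100 in fresh tissue, 19308200 to 25454400 in culture and 17308800 to 27420200 in culture with vesicles. The stated question was how caput vesicles change the transcriptome of corpus explants, with fresh tissue as the control.

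Fresh and cultured tissue were far apart. The first principal component held 63.3% of the variance of log2 CPM and set the 5 fresh libraries against the 10 cultured ones. Across genes, log2 CPM correlated at 0.952 to 0.969 between fresh libraries and at 0.737 to 0.848 between culture and fresh tissue. Same-numbered libraries of the 2 cultures correlated at a median of 0.980. Culture 3 stood apart on the second component (9.34% of the variance), at -137. In this library the 13 mitochondrially encoded protein genes took 0.179% of counts (95% Wilson interval 0.178 to 0.181), against 6.23% to 7.48% in the other 4 cultures.

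**Figure D1:**
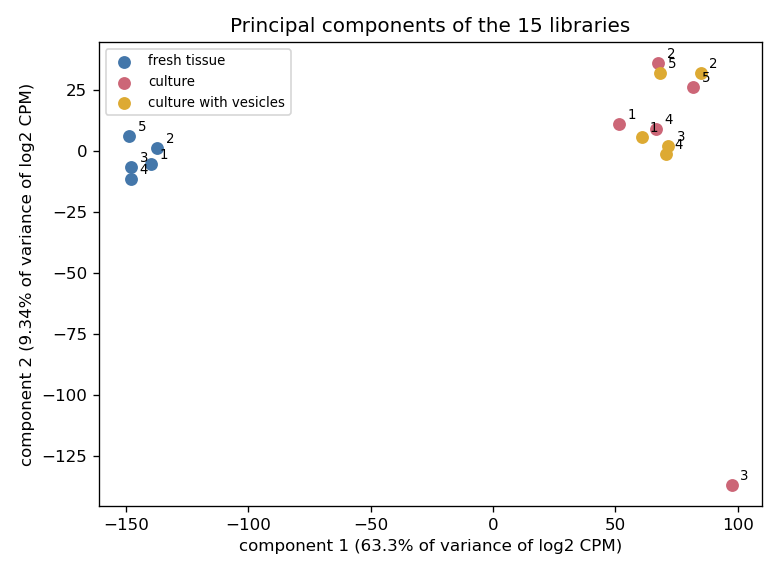
Principal components of log2 CPM for the 15 libraries, with the share of variance on each axis; each point is a library with its replicate number, coloured by group. Fresh tissue lies at the left end of component 1, both cultures at the right, and culture 3 at -137 on component 2.

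The mitochondrial share of counts, which reads from the respiratory chain subunits encoded in the organelle, was 10.1% ± 1.25 (SD, n = 5) in fresh tissue, 5.52% ± 3.03 in culture and 6.84% ± 0.388 in culture with vesicles. Both cultures were below fresh tissue (exact permutation test, p = 0.00794, the smallest that 5 against 5 libraries can give, and adjusted p = 0.0254 over 16 tests of library measures). These tests regroup libraries freely, and so leave out the pairing of culture with vesicles and fresh tissue by number. Without culture 3 the culture share was 6.86% ± 0.598. Ribosomal protein genes took 2.97% ± 0.216 of counts in fresh tissue, 4.20% ± 0.599 in culture (exact p = 0.00794, adjusted p = 0.0254) and 3.84% ± 0.378 in culture with vesicles (exact p = 0.0159, adjusted p = 0.0423).

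**Figure D2:**
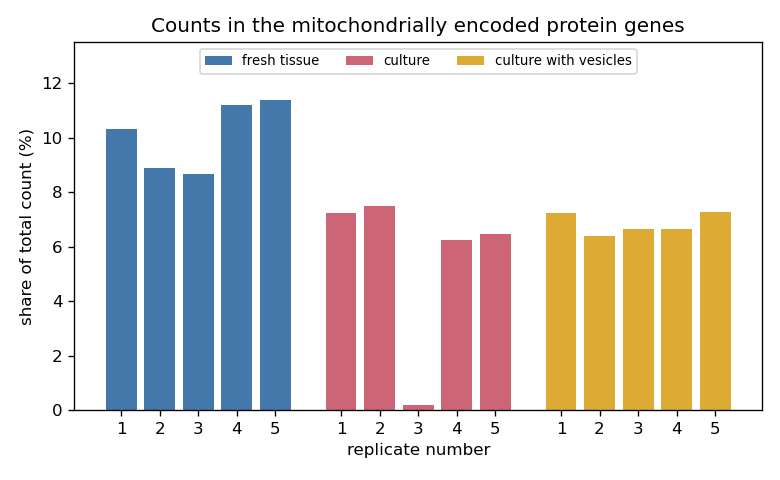
Share of each library's total count, in percent, in the 13 mitochondrially encoded protein genes, by group and replicate number. Fresh libraries lie between 8.69% and 11.4%, and culture 3 at 0.179%.

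The comparison of culture with fresh tissue asks what explant culture itself does to the corpus. In cultured explants most transcripts of epididymal secretory proteins were lower, and most genes for cell division, glycolysis, matrix breakdown and basal epithelium higher, though as lists none passed with an estimated correlation of genes in all 10 libraries (adjusted p of 0.0567 or more). NPC2, a cholesterol-binding protein secreted into the duct (gene 101094270), fell 25.7-fold (log2 -4.68 ± 0.24, SE, n = 5 per group; edgeR adjusted p = 4.10e-09). CRISP1, a sperm-coating protein (gene 101082060), fell 4.42-fold (adjusted p = 3.83e-05). MKI67, a marker of dividing cells, rose 29.4-fold (adjusted p = 2.46e-07), and the basal keratin KRT5 (gene 101100735) rose by 3.09 ± 0.42 on the log2 scale (adjusted p = 1.90e-05). Of 18038 genes tested, 9786 were called, 5175 higher and 4611 lower in culture, of which 3433 and 3135 differed by more than 2-fold.

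Among the largest rises were S100A9 and S100A8, calcium-binding proteins abundant in neutrophils and also made by stressed epithelium. S100A9 (gene 101084419) had 0 counts in fresh tissue and was at least 13679-fold higher in culture, and TCN1, a vitamin B12 carrier, likewise at least 3938-fold. Other large rises were in S100A8 (12.50 ± 0.75, log2 fold change ± SE), the antimicrobial peptide DEFB1 11.62 ± 0.70, PLET1 10.69 ± 0.71, SPINK4 10.06 ± 0.89, the collagenase MMP13 (gene 493679, 9.73 ± 0.76) and CYP24A1, which breaks down vitamin D (9.70 ± 0.66). Among the largest falls were those of SPINK14, -11.26 ± 0.75, RNASE11 (gene 101091454, -8.53 ± 0.53), PATE3 -8.04 ± 0.95, RNASE12 -7.96 ± 0.85, SLC26A7 -7.91 ± 0.66, WFDC9 -7.81 ± 0.58, PDE6A -7.81 ± 0.71 and CD52 (-6.91 ± 0.49), many of them products of the epididymal epithelium. These 16 genes had adjusted p of 6.56e-05 or less. By the rule that picked them, each moved the same way in 5 of 5 same-numbered differences. Leaving out 1 library moved some of the values by over 1.5 times. Without the library in brackets they were 13.67 for S100A8 and 11.73 for PLET1 (fresh 4 and fresh 5), 12.71 for DEFB1 and 10.62 for CYP24A1 (fresh 2), 10.57 for MMP13 (fresh 5) and -8.69 for RNASE12 (culture 1). The fitted TCN1 value went from 14.13 to 13.03 without culture 4, which also held all 5 SPINK14 counts in culture (fitted -14.43 without it).

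**Figure D3:**
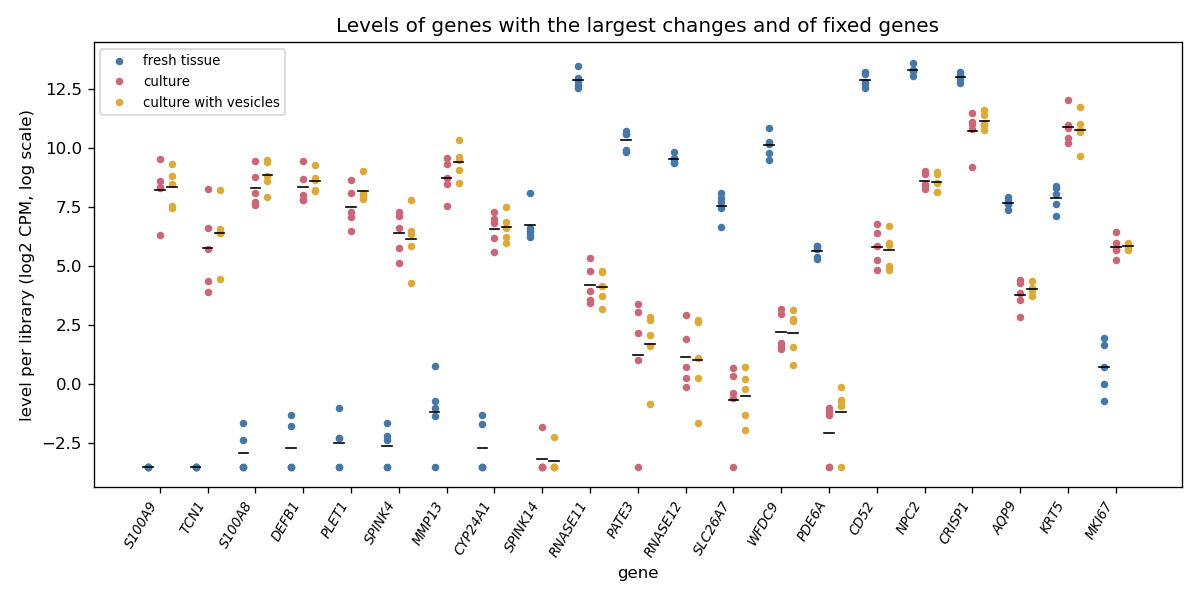
Level per library (log2 CPM) of genes with large changes and of 5 genes fixed beforehand, with points for the 5 libraries of each group, points with 0 counts at the bottom, and bars for group means. NPC2, CRISP1 and AQP9 lie lower in all 10 cultured libraries than in fresh tissue, and KRT5 and MKI67 lie higher.

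Among epididymal secretory proteins, 3 of 35 tested genes rose, 28 fell and 4 did not pass the test (median log2 fold change -3.52; camera adjusted p = 5.03e-11, and adjusted p = 0.0567 with an estimated correlation). RNASE10 -4.52 ± 0.22 (gene 101081471), NPC2 and RNASE11 had the smallest p. GPX5, a secreted antioxidant enzyme, fell by 4.89 on the log2 scale (SE 1.04, adjusted p = 0.000996; -3.98 without fresh 3 and -5.87 without culture 4). The 3 members that rose were the chaperone CLU 3.24 ± 0.49, the protease inhibitor WFDC2 1.83 ± 0.34 and MFGE8 1.76 ± 0.25, and their largest adjusted p was 0.000316. Principal cells, the absorptive and secretory cells of the duct, had 8 of 15 markers lower, 3 higher and 4 not called (median -1.25; camera adjusted p = 0.0322, and adjusted p = 0.10 with an estimated correlation; 0.0581 without culture 2). AQP9, a water and glycerol channel of these cells, fell 13.8-fold, and the peptidase MME -5.05 ± 0.39 and the anion exchanger SLC26A3 -4.14 ± 0.38 also fell (adjusted p = 4.83e-07 or less). Culture 3 had the lowest mean level of principal cell markers among cultures, 3.69 log2 CPM against 4.13 to 4.30. Sperm and late germ cell transcripts fell as well: 8 of 9 were lower and 1 higher (median -4.28, and -3.37 without fresh 5; camera adjusted p = 0.0111, and adjusted p = 0.321 with an estimated correlation), among them ROPN1 -3.04 ± 0.34, AKAP3 -1.41 ± 0.24 and CAPZA3, which had 0 counts in culture and was at least 62.9-fold lower.

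Basal cells sit at the base of the duct epithelium, and 14 of 16 of their markers rose, 1 fell and 1 was not called (median 2.99; camera adjusted p = 5.45e-08, and adjusted p = 0.10 with an estimated correlation). Among them were SFN 6.47 ± 0.53, which marks stratified epithelium, and TRIM29 4.23 ± 0.36. General epithelial markers went both ways, with 10 higher, 3 lower and 7 not called (median 0.50, camera adjusted p = 0.407). Among them KRT7 4.15 ± 0.45 rose, PAX2 -2.14 ± 0.20 fell, and EPCAM had -0.30 ± 0.18 (adjusted p = 0.169). Without culture 3, SFN was 5.72 and KRT7 3.56. Of 24 junction genes 15 rose, 2 fell and 7 were not called (median 0.84; camera adjusted p = 0.0217, and adjusted p = 0.588 with an estimated correlation). Among these, CLDN2, which forms cation-permeable pores, was 1745 times higher (95% interval 483 to 14417; 2 counts in fresh tissue, both in fresh 3; fitted log2 10.31, and 9.70 without culture 4), NECTIN1 3.20 ± 0.28 rose and CLDN8 -3.25 ± 0.34 fell. Clear cells, which acidify the lumen, had 6 markers higher, 3 lower and 5 not called (median -0.05, camera adjusted p = 0.715, with the mean and the test on the upper side). CA2 4.42 ± 0.54 rose and ATP6V1C2 -2.73 ± 0.34 fell (adjusted p = 8.38e-06 or less). Ciliated cell markers had 1 higher, 2 lower and 5 not called (median -0.53, camera adjusted p = 0.550), with FOXJ1 -1.50 ± 0.29 and RSPH1 -1.34 ± 0.34 lower.

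**Figure D4:**
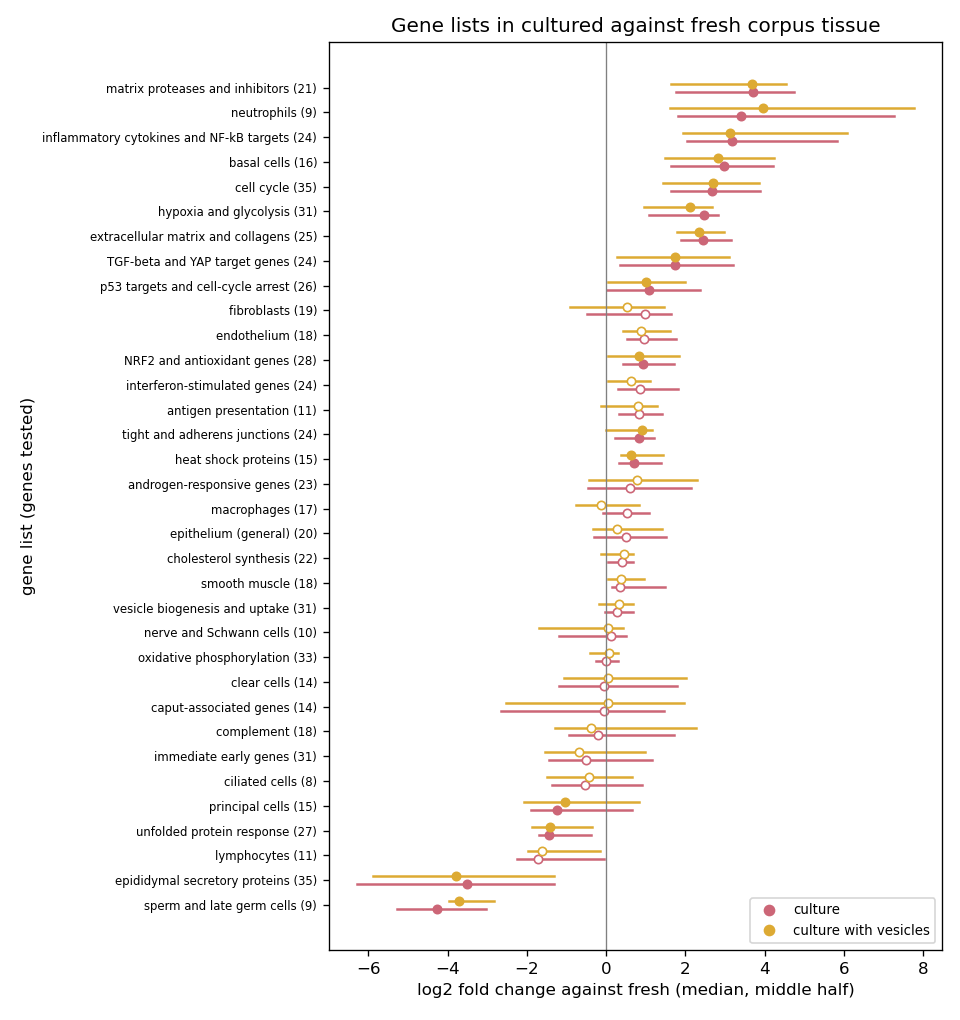
Median log2 fold change against fresh tissue of each of the 34 tested gene lists, in culture and in culture with vesicles, with lines from the lower to the upper quartile of each list's genes; filled points are lists called by camera and open points are not. Cell cycle (median 2.68 in culture) lies on the higher side and secretory proteins (-3.52) on the lower side in both cultures.

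Genes of the cell cycle rose almost together: 31 of 35 were higher, 1 lower and 3 not called (median 2.68; camera adjusted p = 1.99e-20, and adjusted p = 0.0567 with an estimated correlation). KIF20A 4.99 ± 0.29 and TOP2A 4.92 ± 0.30, used in mitosis, and the replication helicase subunit MCM6 2.68 ± 0.16 had the smallest p, and without culture 5 the list passed with an estimated correlation (adjusted p = 0.0250). Hypoxia and glycolysis genes had 27 of 31 higher and 0 lower (median 2.47; camera adjusted p = 1.93e-17, and adjusted p = 0.0567 with an estimated correlation), and the smallest p were those of the glycolytic enzyme PGAM1 2.82 ± 0.12, the glucose transporter SLC2A1 2.92 ± 0.16 and GAPDH 2.33 ± 0.14. Targets of p53, which halts division after damage, had 17 of 26 higher and 3 lower (median 1.08; camera adjusted p = 0.000107, and adjusted p = 0.122 with an estimated correlation), with SERPINB5 5.45 ± 0.32, AEN 3.19 ± 0.19 and the death receptor FAS 2.47 ± 0.22. Nuclear genes of oxidative phosphorylation were mixed, with 6 higher, 9 lower and 18 not called (median 0.00, camera adjusted p = 0.641), or 5 and 5 when adjusted over the list alone. NDUFA1 -1.49 ± 0.16 and NDUFA2 -1.35 ± 0.18 fell (adjusted p = 1.71e-05 or less).

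The unfolded protein response list, made of chaperones and folding enzymes of the endoplasmic reticulum and their regulators, had 19 of 27 genes lower and 5 higher (median -1.44; camera adjusted p = 9.37e-07, and adjusted p = 0.0567 with an estimated correlation). The ubiquitin ligase SYVN1 -1.96 ± 0.12 and the folding enzyme PDIA4 -1.90 ± 0.15 fell. Of the members that rose, 4 belong to the amino acid stress branch: TRIB3 6.49 ± 0.51 (7.12 without fresh 5), CHAC1 2.38 ± 0.49 (3.17 without fresh 4), ASNS 0.90 ± 0.23 and the transcription factor ATF4 0.68 ± 0.18 (adjusted p = 0.00471 or less). Heat shock proteins had 10 of 15 higher and 1 lower (median 0.70; camera adjusted p = 0.000461, and adjusted p = 0.157 with an estimated correlation), with CRYAB 2.44 ± 0.15, HSPB8 3.08 ± 0.28 and the mitochondrial chaperonin HSPD1 1.32 ± 0.11. Fresh 4 had the highest mean level of both lists in fresh tissue, and without it the medians were -1.35 for the unfolded protein response (8.15 log2 CPM in fresh 4 against 7.74 to 7.83 in the other fresh libraries) and 0.83 for heat shock proteins. Antioxidant genes under NRF2 had 18 of 28 higher and 4 lower (median 0.92; camera adjusted p = 0.00201, and adjusted p = 0.157 with an estimated correlation), with SRXN1 4.12 ± 0.34, TKT 2.12 ± 0.19 and thioredoxin (TXN 1.90 ± 0.15).

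Matrix proteases and their inhibitors had 18 of 21 genes higher and 1 lower (median 3.70; camera adjusted p = 5.96e-11, and adjusted p = 0.0749 with an estimated correlation). MMP7 (gene 727698) rose by 9.44 ± 0.43, and the plasminogen activators PLAT 4.96 ± 0.33 and PLAU 3.95 ± 0.30 rose too (adjusted p = 6.36e-08 or less). Matrix and collagen genes had 22 of 25 higher and 0 lower (median 2.45; camera adjusted p = 0.000132, and adjusted p = 0.588 with an estimated correlation), among them LAMC1 2.00 ± 0.22, LAMB1 2.05 ± 0.26 and the collagen cross-linker LOXL2 5.21 ± 0.68. TGF-beta and YAP targets had 16 of 24 higher and 1 lower (median 1.73; camera adjusted p = 4.24e-05, and adjusted p = 0.253 with an estimated correlation), including the feedback inhibitors PMEPA1 4.81 ± 0.28 and SMAD7 2.74 ± 0.25 and the activin subunit INHBA 5.37 ± 0.55. Inflammatory cytokines and NF-kB targets had 20 of 24 higher and 0 lower (median 3.18; camera adjusted p = 1.04e-06, and adjusted p = 0.321 with an estimated correlation), with NFKB1 2.11 ± 0.15, IL11 8.62 ± 0.86 and the adhesion molecule ICAM1 2.98 ± 0.31. The list stood highest in fresh 4 among fresh libraries, and its median was 3.30 without it. The cytokine IL6 rose by 6.41 ± 1.45 (adjusted p = 0.00165, and 0.0836 with limma-voom). Fresh 4 held 36 IL6 counts and the other 4 fresh libraries 0 (fitted 12.50 without fresh 4), and without culture 2 the value was 5.43. Neutrophil markers had 8 of 9 higher and 1 lower (median 3.40, and 4.00 without fresh 3; camera adjusted p = 4.91e-05, and adjusted p = 0.0567 with an estimated correlation). The risers included S100A8, S100A9 and MMP9 4.74 ± 0.49, which epithelium can also make, while CAMP -1.50 ± 0.36, a granule peptide, fell.

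Among the other cell types no list passed the test, though single markers did. Endothelial markers had 8 of 18 higher and 0 lower (median 0.97, camera adjusted p = 0.0631, and 0.0350 without fresh 1 or 0.00561 without culture 4), with CDH5 2.41 ± 0.38 and ESM1 5.49 ± 0.69. Fibroblast markers had 6 higher, 2 lower and 11 not called (median 0.99, camera adjusted p = 0.594), with PDGFRB 2.83 ± 0.45 higher and SCARA5 -3.50 ± 0.49 lower. Smooth muscle had 6 higher and 1 lower of 18 (median 0.36, camera adjusted p = 0.345), with SMTN 1.99 ± 0.33 and CASQ2 2.70 ± 0.45 higher, and ACTA2, smooth muscle actin, at 0.70 ± 0.48 (adjusted p = 0.235). Macrophage markers had 3 higher and 1 lower of 17 (median 0.53, camera adjusted p = 0.413), with CD14 3.61 ± 0.40 and CD68 4.30 ± 0.54 higher. Lymphocyte markers had 0 higher and 4 lower of 11 (median -1.72, camera adjusted p = 0.246), with CD8A -4.56 ± 0.96 (-6.04 without culture 5) and IKZF1 -1.72 ± 0.39 lower. Nerve and Schwann cell markers had 0 higher and 2 lower of 10 (median 0.11, with the mean and the test on the lower side, camera adjusted p = 0.640), with the adhesion molecule NCAM1 -2.06 ± 0.30 lower. Without culture 2, where this list stood highest among the cultures, its median was -0.0196.

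Further lists did not pass the test either. Androgen-responsive genes had 10 higher, 5 lower and 8 not called (median 0.61, camera adjusted p = 0.262), with PMEPA1 and SLC45A3 4.15 ± 0.27 higher. Caput-associated genes had 5 higher and 6 lower of 14 (median -0.06, camera adjusted p = 0.293), with RNASE10 and PEMT -2.47 ± 0.17 lower. Vesicle biogenesis and uptake genes had 10 higher and 6 lower of 31 (median 0.28, camera adjusted p = 0.313), with ANXA2 3.12 ± 0.18 and FLOT2 1.75 ± 0.13 higher. Cholesterol synthesis had 6 higher and 4 lower of 22 (median 0.40, camera adjusted p = 0.345), with HMGCS1, an early enzyme of the pathway, lower (-0.74 ± 0.18, adjusted p = 0.00254). Interferon-stimulated genes had 9 higher and 0 lower of 24 (median 0.86, camera adjusted p = 0.125, and 0.0350 without fresh 1), with OAS2 2.94 ± 0.38 and SAMHD1 3.39 ± 0.57 (2.45 without culture 5). Antigen presentation had 5 higher and 2 lower of 11 (median 0.84, camera adjusted p = 0.279), with PSMB8 2.13 ± 0.27 and CIITA 1.78 ± 0.25. Immediate early genes had 9 higher and 11 lower of 31 (median -0.51, camera adjusted p = 0.655), with FOSL2 2.00 ± 0.23 higher and EGR3 -4.17 ± 0.48 (-3.45 without fresh 4) lower. Complement had 5 higher and 4 lower of 18 (median -0.20, with the mean and the test on the upper side, camera adjusted p = 0.715), with CFI 3.80 ± 0.26 and CLU higher.

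In sum 16 of 34 lists were called in culture against fresh tissue, 12 higher and 4 lower, and 0 with an estimated correlation (1 without culture 5). Adjusted over the list alone, the counts of called members were equal in 22 of 34 lists and shifted by at most 4 genes elsewhere. Of the genes fixed beforehand, 3 had calls that rest on few libraries. CD9, a vesicle surface protein, rose by 0.45 ± 0.15 (adjusted p = 0.0200, and up to 0.0534 without culture 4, fresh 5 or culture 5; 0.0601 under upper-quartile scaling). PTPRC, carried by all white blood cells, was at -1.18 ± 0.40 (adjusted p = 0.0198, and 0.0732 without fresh 5). ATP6V1B1, a proton pump subunit of clear cells, was at -1.84 ± 0.75 (adjusted p = 0.0490), lost its call without any 1 of 11 libraries (adjusted p up to 0.130) and in other fits such as limma-voom (0.261), and was -2.60 without culture 4.

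Culture with vesicles against culture asks what the caput vesicles add. No single gene passed the test between explants with and without vesicles. Camera called 5 gene lists, but 77 of 100 splits of the 10 libraries into 5 and 5 called as many, the real one included. Most of these splits put both libraries of some number on the same side, and so hold differences between replicate numbers. Among the 16 splits that part every same-numbered pair, 7 called as many, the real one included. With an estimated correlation or fry 0 lists were called, so chance cannot be excluded for these shifts. RNASE10, a caput-associated secreted protein, came first when genes with a symbol were ordered by p, at 0.74 ± 0.20 (log2 fold change ± SE, n = 5 per group; higher in 5 of 5 pairs, edgeR quasi-likelihood test, adjusted p = 1). CA9, a carbonic anhydrase induced by low oxygen (gene 101092802), was at -0.81 ± 0.31, lower in 5 of 5 pairs (adjusted p = 1). As a group, hypoxia and glycolysis genes lay lower with vesicles, by a median of -0.30 over 31 genes (camera adjusted p = 1.28e-11, and adjusted p = 0.364 with an estimated correlation). For this list 5 of 100 splits gave a camera adjusted p as small, down to 1.06e-14, the real one included. Among the 16 that part every pair it was 1, the real one.

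Of 18038 genes, edgeR called 0, with 183 at an unadjusted p under 0.05. Independent libraries would give about 901.9 by chance, but same-numbered libraries deviate together, so 901.9 is no exact value for no change. Among the 16 splits of the cultures that part every same-numbered pair, 11 gave as many as the real one, itself included. With fewer small p than 901.9, the test may be too cautious here, and 0 calls do not show that no gene changed. DESeq2 also called 0 (269 at p under 0.05), as did limma-voom (237), the fit with the replicate number as a block (206), the fit without culture 3 (155) and the fit with both (326). The 95% interval of the fold change lay within 2-fold either way for 64.2% of genes and within 1.5-fold for 32.1%. The other genes with the smallest p were CD1H11orf71 -0.81 ± 0.22, the opioid precursor PENK -0.98 ± 0.28, ENKD1 -0.76 ± 0.24, HEATR1 0.32 ± 0.11, MEGF6 -1.37 ± 0.51, KASH5 -0.96 ± 0.36, SNCB -1.49 ± 0.55 and the mitophagy receptor BNIP3 -0.49 ± 0.19, all with adjusted p = 1. MEGF6 was at 3.97 log2 CPM in culture 3 and at most 1.68 in the other cultures. Without culture 3, MEGF6 was at -0.37, SNCB at -0.79 and CA9 at -0.33. The named fixed genes also had adjusted p = 1: GPX5 0.97 ± 0.95, IL6 0.90 ± 1.07, CRISP1 0.30 ± 0.30, HMGCS1 0.27 ± 0.18, CD9 0.15 ± 0.15, AQP9 0.15 ± 0.23, MKI67 -0.02 ± 0.35, ACTA2 -0.05 ± 0.48, NPC2 -0.06 ± 0.21, ATP6V1B1 -0.08 ± 0.74, KRT5 -0.14 ± 0.39 and PTPRC -0.41 ± 0.39. GPX5 kept its sign but ranged from 0.106 to 2.20 over the 32 alternatives. Leaving out culture 3 turned the sign of AQP9 (-0.0311), MKI67 (0.17) and KRT5 (0.25), and leaving out culture with vesicles 2 that of IL6 (-0.77), MKI67 (0.00936), NPC2 (0.0278), ATP6V1B1 (0.18) and KRT5 (0.0329). The sign also turned for NPC2 without culture 1 (0.0433), culture 2 (0.0136) or culture with vesicles 4 (0.0256), for ATP6V1B1 without culture 1 (0.0519), culture 4 (0.67) or culture with vesicles 1 (0.0374), and for ACTA2 without culture 2 (0.41) or culture with vesicles 3 (0.0731), 4 (0.16) or 5 (0.0492).

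Gene lists gave small shifts, and camera called 5 of 34 without any single member being called. Leaving out 1 of the 10 libraries gave 2 to 11 called lists, and of the 5 lists only hypoxia and glycolysis was called each time (median -0.38 to -0.19, camera adjusted p of 5.24e-05 or less, and 0.262 or more with an estimated correlation). Among the lower hypoxia and glycolysis genes were CA9, BNIP3, PGK1 -0.43 ± 0.18 and ALDOC -0.41 ± 0.18. Fibroblast markers were lower (median -0.40 over 19; camera adjusted p = 0.0203, and adjusted p = 0.994 with an estimated correlation), with the matrix genes COL1A1 -0.86 ± 0.77, COL1A2 -0.84 ± 0.67 and FBLN1 -0.67 ± 0.56 and the receptor SCARA5 -0.75 ± 0.47. Without culture 2, COL1A1 was at -0.33, FBLN1 at 0.0908 and the list median at 0.25 (camera adjusted p = 0.827). The list also lost its call without culture with vesicles 1 (0.216), 3 (0.0855) or 4 (0.647) and had a median of -1.04 without culture with vesicles 2. Macrophage markers were lower (median -0.39 over 17; camera adjusted p = 0.0229, and adjusted p = 0.994 with an estimated correlation), with the complement subunits C1QC -1.11 ± 0.70, C1QB -0.75 ± 0.52 and C1QA -0.68 ± 0.56 and the adaptor TYROBP -0.66 ± 0.44. Their call ended without culture 2 (camera adjusted p = 0.827), culture 5 (0.295) or culture with vesicles 4 (0.676). Caput-associated genes were higher (median 0.21 over 14; camera adjusted p = 0.0203, and adjusted p = 0.364 with an estimated correlation), with RNASE10, PROM1 1.77 ± 0.74, PEMT 0.30 ± 0.16 and DUSP6 0.25 ± 0.22. PROM1 was at 0.31 without culture with vesicles 2, and the list lost its call without culture 1 (camera adjusted p = 0.0870), 2 (0.0740) or 5 (0.0639) or culture with vesicles 5 (0.117), and with the fibroblast level as a covariate (0.0555). Cholesterol synthesis was higher (median 0.16 over 22; camera adjusted p = 0.0455, and adjusted p = 0.994 with an estimated correlation), with HMGCS1 and SQLE 0.25 ± 0.19, while PMVK had -1.39 ± 0.58, and 0.0453 without culture 3. This list lost its call without culture 1 (camera adjusted p = 0.274) or 5 (0.481) or culture with vesicles 1 (0.216), 2 (0.296) or 4 (0.275), and with the fibroblast covariate (0.0941). Every member had adjusted p = 1, and adjusted over the list alone 1 gene passed, RNASE10 in the caput list (adjusted p = 0.0264). The other 29 lists had medians of -0.26 to 1.02 and camera adjusted p of 0.0656 or more. Interferon-stimulated genes had the lowest of these medians and were called lower without culture 2, 3 or 4 or culture with vesicles 1, 2 or 5. Without culture 3 their median was -0.47 (camera adjusted p = 7.29e-05, and adjusted p = 0.954 with an estimated correlation). Matrix genes were called lower without culture 1 or 4 or culture with vesicles 2 or 5 (camera adjusted p of 0.0304 or less). With an estimated correlation 0 lists were called in each of the 10 fits without 1 library.

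Over same-numbered pairs, the mean level of hypoxia and glycolysis genes was lower with vesicles in 5 of 5 pairs, by -0.274 ± 0.108 log2 CPM (SD; exact sign-flip test, p = 0.0625, the smallest that 5 pairs can give). Fibroblast and macrophage levels were lower in 4 of 5 pairs and cholesterol synthesis was higher in 4 of 5 (exact p = 0.125 each), and caput genes were higher in 4 of 5 (exact p = 0.312). With the replicate number as a block, 7 lists were called, the same 5 and in addition smooth muscle (adjusted p = 0.00459) and matrix genes (0.0103), both lower with vesicles, and 0 lists with the block and an estimated correlation or fry. Without replicate 1, camera at the preset correlation called 3 lists.

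**Figure D5:**
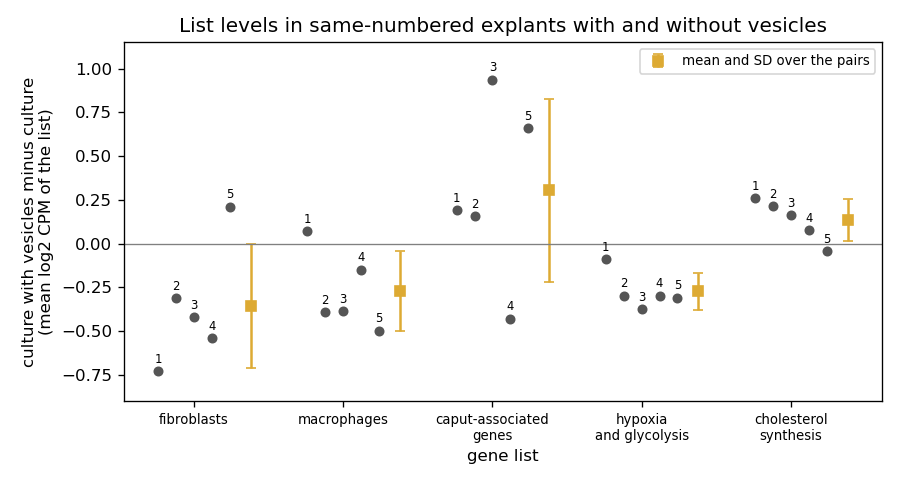
Culture with vesicles minus culture, in mean log2 CPM of the list, for the 5 same-numbered pairs and the 5 lists called by camera; squares and lines give the mean and SD over pairs. Hypoxia and glycolysis genes lie below 0 in 5 of 5 pairs.

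Culture with vesicles against fresh tissue asks for the combined change. In explants with vesicles, too, most secreted epididymal products were lower than in fresh tissue and most division, glycolysis and protease genes higher, though as lists none passed with an estimated correlation (adjusted p of 0.0641 or more). NPC2 was at -4.74 ± 0.25 and CRISP1 at -1.85 ± 0.31 (log2 fold change ± SE, n = 5 per group; edgeR adjusted p = 4.71e-09 and 0.000138), while MKI67 was at 4.86 ± 0.42 and KRT5 at 2.94 ± 0.42 (adjusted p = 2.44e-07 and 2.86e-05). Of 18038 genes 9549 were called, 4950 higher and 4599 lower, of which 3242 and 3173 differed by more than 2-fold.

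Among the largest rises were those of S100A9 (0 counts in fresh tissue, at least 13651-fold), TCN1 (at least 4431-fold), the macrophage elastase MMP12 (0 counts in fresh tissue, at least 2423-fold), S100A8 12.97 ± 0.75, DEFB1 11.78 ± 0.70, PLET1 11.21 ± 0.72, MMP13 10.38 ± 0.77 and SPINK4 10.02 ± 0.89. Among the largest falls were those of SPINK14 (4606 times lower, 95% interval 1576 to 22337, 3 counts in culture with vesicles), CLPSL2 -9.05 ± 0.65, RNASE11 -8.69 ± 0.53, PATE3 -8.30 ± 0.96, SLC26A7 -7.96 ± 0.67, RNASE12 -7.87 ± 0.84, WFDC9 -7.79 ± 0.57 and DHRS2 -7.40 ± 0.71. Their largest adjusted p was 5.85e-05. Without 1 library, values moved by over 1.5 times for S100A8 (14.13, fresh 4), DEFB1 (12.87, fresh 2), PLET1 and MMP13 (12.25 and 11.22, fresh 5), SPINK4 (9.40, culture with vesicles 4) and CLPSL2 (-10.25, culture with vesicles 1). Fitted values went from 14.37 to 13.63 for TCN1 without culture with vesicles 4, and from 13.63 to 12.97 for MMP12 without culture with vesicles 2. All 3 SPINK14 counts lay in culture with vesicles 3 (fitted -14.43 without it). Other fixed genes that passed were AQP9 -3.64 ± 0.26, GPX5 -3.92 ± 0.99, IL6 7.31 ± 1.49, CD9 0.59 ± 0.15 and PTPRC -1.59 ± 0.40 (adjusted p = 0.00358 or less). GPX5 was -3.00 without fresh 3 and -4.53 without culture with vesicles 5. IL6 was 5.62 without culture with vesicles 2 (fitted 13.39 without fresh 4) and had an adjusted p of 0.0661 with limma-voom. HMGCS1 -0.47 ± 0.18 (adjusted p = 0.0358) lost its call without any 1 of 4 libraries, fresh 3, 4 or 5 or culture with vesicles 5 (adjusted p up to 0.0807), and without a filter (0.0782). ATP6V1B1 -1.92 ± 0.75 (adjusted p = 0.0424) lost it without any 1 of 8 libraries (up to 0.114) and with limma-voom (0.101), and ACTA2 0.65 ± 0.48 did not pass (adjusted p = 0.272).

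The same 16 lists were called as in culture without vesicles, 12 higher and 4 lower, and 0 with an estimated correlation (adjusted p of 0.0641 to 0.669). Secretory proteins had 29 of 35 genes lower and 4 higher (median -3.78; camera adjusted p = 6.10e-11, and adjusted p = 0.0641 with an estimated correlation). Cell cycle genes had 31 of 35 higher and 2 lower (median 2.70; camera adjusted p = 4.44e-21, and adjusted p = 0.0641 with an estimated correlation), and hypoxia and glycolysis genes 26 higher and 1 lower (median 2.13; camera adjusted p = 1.85e-13, and adjusted p = 0.0892 with an estimated correlation). Basal cell markers had 14 of 16 higher (median 2.83; camera adjusted p = 4.85e-08, and adjusted p = 0.0892 with an estimated correlation) and principal cell markers 8 of 15 lower and 3 higher (median -1.04; camera adjusted p = 0.0319, and adjusted p = 0.0993 with an estimated correlation; 0.0533 and 0.0541 without culture with vesicles 1 or 2). Matrix proteases and inhibitors had 18 of 21 higher and 1 lower (median 3.68; camera adjusted p = 6.10e-11, and adjusted p = 0.0892 with an estimated correlation). The 18 uncalled lists had camera adjusted p of 0.0867 or more, where endothelial markers were at 0.0494 without fresh 1 and at 0.0409 or 0.0181 without culture with vesicles 1 or 4. Adjusted over the list alone, the counts of members were equal in 21 of 34 lists and shifted by at most 3 genes elsewhere.

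Both cultures shared most of their changes from fresh tissue. Of the genes called higher, 4559 were called in both comparisons, which share the 5 fresh libraries, and of those called lower 4156. No gene was called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.982, against 0.499 in simulations of unchanged, independent libraries that share the fresh ones. With the fresh libraries split by replicate number between the comparisons the mean correlation was 0.915 (SD 0.0208 over 20 splits). The covariance was 2.58, against 0.0843 simulated, a difference of 2.49.

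Whether vesicles moved explants towards fresh tissue or away from it was asked by setting the vesicle effect against the culture effect across genes. The 2 effects correlated at -0.121, where shared culture libraries alone gave -0.502 in simulations of independent libraries. The simulations leave out that same-numbered libraries deviate together, so -0.502 is no exact value for no change. With each effect taken from other replicate numbers the mean correlation was 0.0334 (SD 0.110, range -0.103 to 0.262 over 20 splits), so neither direction was detectable.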

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

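The test of the replicate number of culture 3 was chosen before its result was seen, and the tests of its depth and of its mix of cells after. In each group of 5 libraries, a value was taken to stand apart when its gap to the nearest other library exceeded 0.71 of the group's range (Dixon's 95% critical value). Of 240 groups of values, 20 had such a value, where chance gives about 1 in 20, or 12. They fell in fresh tissue (7), culture (7) and culture with vesicles (6), and 3 of them in culture 3.

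In fresh tissue, fresh 4 stood apart in SPINK14 (8.10 log2 CPM, highest) and IL6 (1.12, where the other 4 had 0 counts), and in the mean log2 CPM of inflammatory genes (1.87), unfolded protein response genes (8.15) and heat shock proteins (6.41), each the highest of the 5. Fresh 5 had the lowest mean of principal cell markers (4.86 log2 CPM). In fresh 3 the 10 most abundant genes took the lowest share of counts, 10.6%.

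In culture, the mitochondrial share (0.179%) and the principal cell markers (3.69 mean log2 CPM) of culture 3 were the lowest of the 5, and its MEGF6 level (3.97 log2 CPM) the highest. Culture 2 had the highest mean of nerve and Schwann cell markers (2.79) and culture 5 of antigen presentation genes (5.86). SPINK14 in culture 4 (-1.79 log2 CPM, 5 counts) and CLPSL2 in culture 1 (-2.27, 3 counts) stood apart from 4 libraries with 0 counts. In culture with vesicles, the 10 most abundant genes took 16.9% of counts in replicate 4, the highest share. Replicate 5 had the lowest mean of oxidative phosphorylation genes (6.0) and of immediate early genes (5.23). In replicate 3 PLET1 was highest (9.01 log2 CPM), SPINK14 had 3 counts (-2.25) where the others had 0, and PDE6A was lowest (-3.49, 0 counts).

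Culture 3 lay far from the other cultures in its mitochondrial genes. Lower depth is argued against by its total count of 20.6 M, which lies between those of the other cultures. It had the fewest genes with a count, however, 18900 against 20304 to 22181 in the other libraries. Depth does not account for this lower number, and its cause was not tested. Another mix of cells would lower the 13 mitochondrial genes alike, but they ranged over 7.82 log2 units against the other cultures (0.752 at most in any other library), from -4.15 for ND6 to -11.97 for ATP8. A sample of another replicate number is argued against by the 360 genes particular to number 3 in the other groups, of which 75.8% deviated the same way in culture 3 and at most 46.7% in any other culture. A loss in library preparation that depends on the transcript's sequence stays open, since no GC content was computed. Apart from the mix of cells, no biological explanation was tested.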

How the results depend on the processing

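Added after the data were seen were the fits without each library for lists, without culture 3 with the block, without mitochondrial genes, and with the fibroblast covariate; the other alternatives were planned. The number of genes called ranged from 6278 to 12176 in culture against fresh tissue and from 6084 to 12802 in culture with vesicles against fresh tissue. The lowest counts, 6278 and 6084, came with the test against a 1.5-fold change, which asks for more than a difference. The number was 0 for culture with vesicles against culture under all 32 alternatives. Of the values of named genes under alternatives, 3417 of 3455, 1143 of 1183 and 871 of 896 kept direction and side of the threshold (culture against fresh, the 2 cultures, vesicles against fresh). Of the rest, 35 and 25 lost a call against fresh tissue, 3 gained one and 40 changed sign between the cultures, where no gene was called. Calls of CD9, HMGCS1, PTPRC, ATP6V1B1, ATF4 and ASNS in culture against fresh ended with the test against 1.5-fold, as did those of CD9, HMGCS1 and ATP6V1B1 with vesicles. The replicate block called 10438 genes in culture against fresh tissue (9562 in both fits), where the correlation of same-numbered libraries was 0.198, 0.344, 0.265 and 0.290 for replicates 1, 2, 4 and 5 but 0.0326 for replicate 3 (0.0417 with another number), so the numbers were not taken to pair these groups, and 10283 with vesicles against fresh (9418 in both). It brought ACTA2 past the threshold in culture (adjusted p = 0.0281, and 0.0302 and 0.0439 in the other fits with the block). Leaving out culture 3 gave 11090 and 11658 genes, 9358 and 9548 of them also called with it.

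Lists called with an estimated correlation were 0 in each comparison, but 1 in culture against fresh tissue without culture 5 (cell cycle, adjusted p = 0.0250). With fry they were 24 in culture against fresh tissue, 0 between the cultures and 25 with vesicles against fresh. Between the cultures, camera at the preset correlation called 3 to 7 lists when a replicate number was left out (3 without replicate 1) and 2 with the fibroblast covariate. The covariate is the mean level of the fibroblast markers. The move of their median from -0.40 (SD over genes 0.310) to -0.04 (0.276, camera adjusted p = 0.807) was therefore fixed in advance. The median of macrophage markers went from -0.39 (0.339) to -0.15 (0.331, camera adjusted p = 0.446), so that shift itself shrank. The medians of caput genes, 0.21 (0.514) and 0.18 (0.471, camera adjusted p = 0.0555), and cholesterol synthesis, 0.16 (0.361) and 0.18 (0.369, camera adjusted p = 0.0941), moved less than their spread. Their calls ended from adjusted p of 0.0203 and 0.0455. General epithelial markers were called lower with it (median -0.18, adjusted p = 0.0342, and 0.939 with an estimated correlation). The correlation of both culture effects with split fresh libraries was 0.955 over called genes, 0.940 at a mean log2 CPM of 3 or more, and 0.892 to 0.915 when a replicate number was left out. That of the vesicle effect with the culture effect was -0.0217 to 0.0963 in the same fits.

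Log2 fold changes between the cultures changed sign for these genes. Leaving out 1 library or number gave IL6 -0.77 to 1.88, AQP9 -0.12 to 0.33, MKI67 -0.17 to 0.17, ACTA2 -0.66 to 0.41, NPC2 -0.19 to 0.11, ATP6V1B1 -0.46 to 0.67, KRT5 -0.47 to 0.31, FBLN1 -1.22 to 0.0908 and PMVK -1.66 to 0.0453. The 2 cultures alone with the block gave MKI67 0.0209 and ATP6V1B1 0.12. Without culture 3 and with the block, AQP9 was -0.0658, MKI67 0.0525, KRT5 0.24 and PMVK 0.0721. With limma-voom, which gave culture 3 a weight of 0.0709, AQP9 was -0.0706, MKI67 0.18, KRT5 0.15, C1QC 0.22 and PMVK 0.0113. The cause was not tested. Depth limits what can be said of genes near 0 counts, such as SPINK14 with 5 counts in culture.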

Other observations

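The splits of the samples were planned. The other tests here, of the squamous, ribosome biogenesis, mitochondrial, secretory and hypoxia patterns, were chosen after the results were seen. Many transcripts of squamous epithelium, the layered kind that lines skin, were higher in cultured explants. Among 23 such genes, 15 rose, 1 fell and 7 were not called in culture (median 1.53, camera p = 4.04e-05, and p = 0.133 with an estimated correlation), and 13 rose and 1 fell with vesicles (median 1.20, camera p = 4.62e-05, and p = 0.140 with an estimated correlation). The cornified envelope protein IVL rose by 8.45, the keratins KRT6A and KRT16 by 7.48 and 6.38, and the desmosome cadherin DSG3 by 3.87. With the 2 genes at 0 counts in fresh tissue set to their bound the medians were 1.53 and 1.20.

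Of 34 genes of ribosome biogenesis, 20 rose, 0 fell and 14 were not called in culture (median 0.74, camera p = 0.000602, and p = 0.0503 with an estimated correlation). With vesicles 19 rose and 15 were not called (median 0.59, camera p = 0.000736, and p = 0.0524 with an estimated correlation). NPM1, a nucleolar chaperone, rose by 1.53, the assembly factor RRS1 by 2.50 and the pseudouridine synthase DKC1 by 1.00. The squamous and ribosome lists were made after the largest changes had been seen, so their camera p values are no independent test of these patterns.

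Most secretory genes of the duct were lower in both cultures, though as a list they did not pass with an estimated correlation in either. Loss of epithelium as a whole, on the scale of the secretory fall, is argued against by the general epithelial markers, whose lower median was 0.28. Their lower quartile lay above the upper quartile of the secretory genes in both cultures. These markers went both ways in culture, and their level per cell was not measured. A smaller loss, or one hidden by a rise of the markers within cells, is therefore not excluded. Fewer principal cells stay open: their markers had a lower median of -1.25, and the upper quartile of the secretory genes was -1.32, so the spread of the lists does not part a loss of these cells from a fall of transcripts within them. A lower output per cell was not tested apart from this.

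Hypoxia and glycolysis genes lay lower with vesicles than without. Culture 3 alone is argued against by the other 4 pairs, each lower with vesicles (mean -0.249 ± 0.106 log2 CPM, SD); the median without it was -0.19 (camera adjusted p = 4.68e-10, and adjusted p = 0.743 with an estimated correlation). Less stroma as the whole cause is argued against, so far as the fibroblast list measures stroma. With the fibroblast level as a covariate the median of hypoxia genes went only from -0.30 to -0.29 (SD over genes 0.230, camera adjusted p = 4.37e-10). With an estimated correlation the adjusted p was 0.840, where the list did not pass without the covariate either. The covariate is the mean of the fibroblast markers, so the move of their own median from -0.40 to -0.04 was fixed in advance. How well it captures stroma was not tested. A straight line of the list difference on the fibroblast difference was fitted over the 5 pairs. At an equal fibroblast level it gave -0.331 ± 0.0719 log2 CPM (SE, 95% interval -0.560 to -0.102). Only 1 pair had a higher fibroblast level with vesicles, by 0.210, and there the list difference was -0.310. The value at an equal level therefore leans on that pair, and the interval holds only if a straight line is right. Chance cannot be excluded: 5 of 100 splits of the 10 libraries gave an adjusted p as small, down to 1.06e-14. Most of these 100 splits put both libraries of some number on the same side, and so hold differences between replicate numbers. Among the 16 splits that part every same-numbered pair, the real one had the smallest (1.28e-11, next 1.05e-08). A share of 1 in 16 does not exclude chance, so an effect of the vesicles stays open.

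The 13 mitochondrially encoded protein genes had negative values in culture with vesicles against fresh tissue (median -0.67, 0 called). Their spread was estimated over all 15 libraries, with culture 3 at -4.15 (ND6) to -11.97 (ATP8) log2 units against the other cultures. The 0 calls therefore do not describe these 2 groups alone. Their share of counts was lower with vesicles than in fresh tissue (exact permutation test without regard to pairs, p = 0.00794). Nuclear genes of oxidative phosphorylation had a median of 0.0684, above the upper quartile of the encoded genes (-0.44), which argues against a general fall of respiratory chain genes.

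Splits of 10 libraries into 5 and 5 were counted in 100 draws, the real one included. For culture against fresh tissue 1 split, the real one, called as many genes as that (9786, highest other 895). The same held for culture with vesicles against fresh tissue (9549, highest other 1). No other split drawn gave counts as large, though each mixes fresh and cultured libraries, which widens the spread within its groups. Between the cultures the real split called 0, which all 100 splits reach, so this count does not bear on chance. Another split called 171, which points to a structure among the samples apart from the vesicles. For the number of lists called between the cultures, 77 splits called as many as the real 5 (highest other 18). Most of the splits drawn put both libraries of some number on the same side, and so hold differences between replicate numbers. Against fresh tissue, 27 splits called as many lists as the real 16 in culture (highest other 20) and 49 as many as 16 with vesicles (23). Each of these other splits sets unequal numbers of fresh libraries against each other and so holds part of the difference, so for the lists these counts do not decide on chance. Among the 16 splits of the cultures that part every pair, 7 called as many lists, up to 12, so between the cultures chance cannot be excluded.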
